A study of Mus musculus with 48 samples.

How the data were processed

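The series holds 48 mouse libraries: 36 of the histone mark H3K9me3 with their inputs and 12 of H3K27me3. H3K27me3 is the repressive mark deposited by Polycomb repressive complex 2, and chromatin immunoprecipitation sequencing (ChIP-seq) counts the DNA fragments that carry it against an input library made without the antibody. The H3K27me3 part covers 3 cell types, each with 2 ChIP and 2 input libraries: definitive endoderm sorted as ENDM1-positive cells at embryonic day 8.25, hepatocytes of 8-week-old adults, and insulin reporter-positive beta cells at 8 weeks. The H3K9me3 libraries were not analysed here.

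The values used were ratios of H3K27me3 to input, quantile-normalized across cell types by the authors, per the title of the deposited table and its column names. That the values are linear ratios was read from the values themselves, which are above 0 throughout. Reads were handled with Bowtie2 2.1.0 and bedtools on build mm9, per the submitters' processing notes. The region measured for a gene, any constant added to the ratio, and how the 2 ChIP and 2 input libraries of a cell type were combined are not given in the sources used here. The table holds 24466 gene symbols, each once, with 1 pooled value per cell type. Read depth is unknown, and the table carries no spread between replicates. No test across samples was therefore possible, no p-value is given, and each difference compares 3 pooled profiles without a replicate check. The design fixed beforehand called for limma on replicate values and named this description as its replacement for pooled values.

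Quantile normalization gives every column 1 distribution, with a median ratio of 0.711 and an upper quartile of 1.27. Total H3K27me3 can thus not be compared between cell types, and a value states where a gene stands within its own column. In each column 1 value recurs at many genes: 1.27 at 346 genes in endoderm, 0.918 at 357 genes in hepatocytes and 0.932 at 430 genes in beta cells. Genes for microRNAs, snoRNAs and scaRNAs made up 96.5%, 87.7% and 96.5% of them, and ratios of regions without reads would recur in this way.

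Ratios were compared as log2(ratio + 0.0711). The pseudocount was set 10 times below the median ratio, and it shrinks the differences of genes with low ratios. A gene was counted as higher or lower at a log2 difference of at least 1, a 2-fold difference on this scale. For a gene list, the median difference of its members was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean level. A list was said to stand apart when its percentile fell outside the central 95%. The rule was applied to 63 combinations of list and comparison without correction, and 16 stood apart. It leaves 5% outside by chance if genes vary independently, and more if the members of a list share their signal, which was not examined. Calls near the limits are therefore weak. The rule describes these profiles and is not a test between conditions. The calculation was tested on simulated data made from the endoderm column of 24466 genes. Each simulated cell type was that column with random noise added, and known changes were planted in 1 of them. All 50 of 50 genes were recovered at each simulated log2 change of -3, -2, 2 and 3. Of 24266 unchanged genes, 119 were counted, and 5 of 100 unchanged lists stood apart. The noise was set smaller than the spread of the real differences (robust standard deviation 0.75 for hepatocytes against endoderm). These outcomes follow largely from the settings, so they check the calculation and give no error rate for the real profiles.

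The 3 comparisons, the 21 gene lists, the size threshold, the rule for named genes and the main alternatives were chosen before the data were examined. By that rule, the 10 highest and the 10 lowest differences of each comparison were taken among genes at or above the 75th percentile in at least 1 of the 2 cell types, without unnamed gene models, microRNAs and snoRNAs. From each list, up to 4 members with the largest difference could be named, and every member of the hepatic transcription factor, pancreatic endocrine transcription factor and non-beta islet hormone lists. Other list members named are given as exceptions to their list's direction and were picked after their values were seen. Some list members are not reported here by name. Of the fixed names, 1 (Foxf1a) was not found among the symbols. Symbols were looked up in a RefSeq table of assembly GRCm38.p6, where 23415 matched directly and 946 through a synonym, and 105 had no match. Since that assembly differs from mm9, no coordinate, gene length or chromosome was taken from it.

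The alternatives were a pseudocount 10 times smaller or larger, only genes above the median level, rank percentiles with a threshold of 25 points, a threshold 1.5 times as large or of 0.5, random lists not matched on level, and the mean of a list in place of its median. After the data had been seen, 3 more were added. They left out small RNA genes, divided each column by its most frequent value, or left out the hand-listed X-linked and escape genes below. Other X-linked genes stayed in. The pseudocount alternatives were then also run on the lists. A scan of 143 symbol families with at least 15 members, and hand-written lists of 90 X-linked genes, 4 genes that escape X inactivation and 10 Y-linked genes, were likewise made after seeing the data. Intervals for medians of such sets are 95% bootstrap intervals over genes (2000 draws). They treat genes as independent and do not cover the spread between animals. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.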

Results

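H3K27me3 was profiled at 24466 genes in definitive endoderm, the embryonic layer that forms liver and pancreas, and in 2 adult cell types descended from it, hepatocytes and insulin-producing beta cells. Each cell type was represented by 1 pooled, quantile-normalized ratio of ChIP to input per gene. The labels list 2 ChIP and 2 input libraries per cell type, and how these entered the ratio is not given in the sources used here. No value carries a replicate error, and read depth is unknown. Across genes, the Spearman correlation of the ratios was 0.47 between hepatocytes and endoderm, 0.36 between beta cells and endoderm, and 0.49 between the adult cell types. Genes are not independent replicates, so these coefficients only describe the profiles.

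Among the 21 gene lists, Hox genes and neural transcription factors had the highest median ratios in all 3 cell types. All 39 Hox genes, which pattern the body axis, were at or above the 75th percentile of genes in each cell type, with median ratios of 8.21 in endoderm, 6.49 in hepatocytes and 5.89 in beta cells. Of 38 transcription factors of the nervous system, 38, 37 and 36 were at or above that percentile in endoderm, hepatocytes and beta cells, with median ratios of 7.30, 6.30 and 5.76. Mesodermal transcription factors had medians of 3.37, 4.06 and 4.27. Housekeeping genes had medians of 0.45, 0.44 and 0.42, below the median of all genes (0.711).

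The first comparison set adult hepatocytes against definitive endoderm, the baseline of the series, and asked how the mark differs at the hepatic end of development. Genes of the hepatic program carried less H3K27me3 in hepatocytes. Of 17 hepatic transcription factors, 14 were lower and 0 higher, with a median log2 difference of -2.13, below all 10000 random lists. Cebpa, a regulator of liver metabolism, had ratios of 11.3 in endoderm and 0.13 in hepatocytes. Hhex, a homeobox factor needed for liver budding, had 3.38 and 0.10, and Onecut1 had 2.70 and 0.31. Factors under the threshold included Hnf4a (0.75 and 0.46) and Nr1i3 (0.64 and 0.29). Cebpb had the largest difference of the list (140 and 0.35), from an endoderm value in the far upper tail.

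Genes for the functions of mature liver followed the same direction. Of 36 such genes, 24 were lower and 0 higher in hepatocytes, with a median difference of -1.34, again below all random lists. Hp, the hemoglobin-binding plasma protein haptoglobin, had ratios of 2.19 in endoderm and 0.21 in hepatocytes. Hpd, an enzyme of tyrosine breakdown, had 1.94 and 0.20. The fibrinogen chain genes Fgg (0.61 and 0.06) and Fga (0.85 and 0.10) were also lower. Most of these genes were not highly marked in endoderm: the median ratio of the list was 0.83 there and 0.24 in hepatocytes, and 0 of 36 were in the top 5% of endoderm genes.

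Inhibitors of the cell cycle were lower in hepatocytes at 5 of 7 genes and higher at 0, with a median difference of -1.38 at the 0.07th percentile of random lists. Cdkn2c had ratios of 3.09 in endoderm and 0.27 in hepatocytes, and Cdkn2d 0.88 and 0.26. Cdkn2a had high ratios in both (6.20 and 5.75). With rank percentiles in place of ratios, among genes above the median level, and by the mean, this list fell within the random range (percentiles 5.02, 7.32 and 2.96). Genes of fetal liver and fetal growth were higher in hepatocytes at 4 of 10 genes and lower at 0, with a median difference of 0.70 at the 99.1st percentile. H19, an imprinted RNA of fetal tissues, had ratios of 0.59 in endoderm and 3.20 in hepatocytes, and Igf2bp1, an RNA-binding protein of fetal growth, 0.51 and 2.22. The other 6 were under the threshold, among them Dlk1 (3.92 and 3.59) and Afp, which went the other way (0.61 and 0.41). By the mean instead of the median, this list was within the range (90.7th percentile).

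The remaining 17 lists lay within the random range in this comparison. They included beta cell function (median 0.21; 4 higher and 2 lower of 29), pancreatic endocrine transcription factors (-0.11; 1 and 3 of 19), neural transcription factors (-0.16; 0 and 11 of 38), Hox genes (-0.35; 2 and 6 of 39) and beta cell disallowed genes (-0.39; 2 and 6 of 15). In some alternatives 3 of these lists lay below the range. Neural factors did so by the mean (-1.19, 0.20th percentile), and their mean in beta cells was -1.22. Hox genes did so among random lists not matched on level (1.64th percentile), and disallowed genes by the mean (-0.92, 0.27th) and in rank percentiles (0.69th). Pdx1, the master regulator of pancreas, had ratios of 6.39 in endoderm and 7.18 in hepatocytes, and Nkx6-1 had 7.06 and 6.27. Markers of blood and immune cells (-0.12), endothelium (-0.08) and fibroblasts or stellate cells (0.37), other cells of the liver, were within the range as well. The median and mean differed in sign for endoderm progenitor genes (0.18 and -0.18) and gut regional factors (0.29 and -0.04), and likewise for islet hormones (0.50 and -0.003) and blood and immune genes (-0.12 and 0.06). Foxa1, a pioneer factor of endoderm, had ratios of 72.6 and 1.78, while Sox17, an endoderm factor, had 1.42 and 7.05. The rank percentile of Foxa1 was 99.7 in endoderm and 85.8 in hepatocytes.

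Over all genes, 3123 were higher and 3266 lower in hepatocytes than in endoderm. Dividing each column by its most frequent value moves the median of all genes from -0.03 to 0.38, and gives 5215 higher and 1897 lower genes, 73.3% higher in place of 48.9%. The genes furthest below their endoderm level included Natd1 (232 and 0.53), Suv39h2, an H3K9 methyltransferase (210 and 0.63), Olig1 (181 and 0.86), Lrrc26 (185 and 1.84) and Mt1, a metallothionein (10.9 and 0.12). Mafa, a beta cell factor, was among them with 317 and 6.73, but its rank percentile differed by -1.16 points, and that of Lrrc26 by -13.2 points. The genes furthest above it included Scarna10 (1.27 and 630), Zcchc3 (0.02 and 5.28), Sprr4 (0.01 and 4.15) and Ccl12 (0.04 and 2.75). The other 6 of the 10 were olfactory receptor genes, such as Olfr523 (0.05 and 4.12). The endoderm ratio of Scarna10 is the most frequent value of the endoderm column, and the rank percentile of this gene differed by 24.98 points. Olfactory receptors made up 563 of the 3123 higher genes.

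The second comparison set mature beta cells against the same endoderm baseline. Endocrine transcription factors and genes for beta cell function carried less H3K27me3 in beta cells, while islet hormone genes did not stand apart. Of 19 endocrine transcription factors, 14 were lower and 0 higher, with a median difference of -1.24 at the 0.01st percentile. Pdx1 had ratios of 6.39 in endoderm and 0.22 in beta cells. Nkx2-2 (6.18 and 0.23), Nkx6-1 (7.06 and 0.33) and Pax6 (5.34 and 0.26), homeobox factors of islet cells, showed differences of similar size. Neurog3, which acts in endocrine progenitors, had high ratios in both (7.86 and 4.14), as did Fev (9.18 and 3.85). Insm1 (105 and 0.52) and Mafa (317 and 0.68) had the largest differences, from upper-tail endoderm values.

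Of 29 genes for beta cell function, 18 were lower and 1 higher in beta cells, with a median difference of -1.22, below all random lists. Kcnj11, a subunit of the ATP-sensitive potassium channel, had ratios of 3.31 in endoderm and 0.41 in beta cells. Pcsk1n had 3.79 and 0.28, and the synaptotagmin Syt7 had 1.96 and 0.37. The insulin genes did not follow the list: Ins1 was higher (0.05 and 1.56), and Ins2 had 0.38 and 0.59. The Ins1 difference starts from a low endoderm value, at rank percentile 2.36. It was not particular to beta cells, since hepatocytes had ratios of 1.38 at Ins1 and 1.04 at Ins2. Pcsk1n and Sytl4 are X-linked, and 76 of 90 X-linked genes were lower in beta cells than in endoderm (median -1.55). Non-beta islet hormones were within the random range (-0.68; 1 higher and 1 lower of 5). Sst, the hormone of delta cells, was higher in beta cells (1.53 and 4.47), Ghrl was lower (1.71 and 0.61), and Gcg had 1.05 and 1.89.

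Genes that are kept silent in beta cells, called disallowed genes, were higher at 9 of 15 and lower at 0, with a median difference of 1.41 above all random lists. Ldha, lactate dehydrogenase A, had ratios of 0.65 in endoderm and 3.55 in beta cells. Lmo4 had 0.36 and 2.67, Acot7 0.99 and 4.67, and the hexokinase Hk2 0.47 and 2.14. Genes for hepatocyte function were higher in beta cells at 9 of 36 and lower at 2 (median 0.43, 99.8th percentile). The bile acid enzyme Cyp8b1 had 0.40 and 7.37, and Ahsg, a plasma glycoprotein, 0.32 and 2.81. Among genes above the median level, which keep 12 of the 36, the median was 0.13 and within the range (57.3rd percentile). Hepatic transcription factors as a list were within the range (-0.04; 1 higher and 4 lower of 17).

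Fetal liver genes were higher in beta cells too, at 5 of 10 with 0 lower (median 0.71, 98.0th percentile). H19 had ratios of 0.59 and 3.08 and Mycn, a growth regulator, 0.66 and 3.01. By the mean, and with the larger pseudocount, this list fell within the range (92.8th and 95.3rd percentiles). Neural transcription factors were lower at 13 of 38 and higher at 0 (median -0.60, 0.56th percentile). The central 95% of random lists held 3 to 13 lower and 2 to 10 higher genes, so only their count of higher genes lay outside. In rank percentiles the median difference was -0.59 points and within the range (28.9th percentile). Housekeeping genes had a median of -0.35 at the 2.19th percentile, with 8 of 25 lower and 0 higher. Their call ended in 6 of 9 alternatives, among them leaving out hand-listed X-linked genes (-0.28, 6.46th percentile) and dividing by the most frequent value (0.02, 2.69th percentile). The other 14 lists were within the range, including Hox genes (-0.37, but 1.55th percentile among lists not matched on level), cell cycle inhibitors (-0.66, but 1.44th percentile with the larger pseudocount) and pancreatic exocrine genes (0.14; 4 higher and 6 lower of 21). The median and mean differed in sign for the exocrine (0.14 and -0.20), endoderm progenitor (0.14 and -0.19), ligand (-0.02 and 0.03) and blood and immune lists (-0.04 and 0.13). Within the exocrine list, Ptf1a, a factor of acinar cells, had ratios of 139 and 3.67, and Ctrb1, a chymotrypsinogen, 0.46 and 2.81. The rank percentile of Ptf1a stayed high, at 99.8 in endoderm and 96.1 in beta cells.

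In all, 3457 genes were higher and 3694 lower in beta cells than in endoderm. After division by the most frequent value, the median of all genes moves to 0.38, and 5709 genes were higher and 2346 lower, 70.9% higher in place of 48.3%. Besides Mafa and Insm1, the genes furthest below endoderm included Natd1 (232 and 0.59), Suv39h2 (210 and 0.97), Cebpb (140 and 0.90), Sowaha (109 and 0.75), Lrrc10b (12.5 and 0.12) and Znrf4 (163 and 1.70). For Znrf4, Lrrc26 and Foxe3 the rank percentile differed by fewer than 25 points. The genes furthest above endoderm included Scarna2 (0.01 and 11.8), Rprl1 (0.05 and 9.95), Ccl12 (0.04 and 5.55), Ackr1, a chemokine receptor of red cells and vessels (0.06 and 5.49), and 3 olfactory receptors, among them Olfr792 (0.23 and 44.4). Olfactory receptors made up 527 of the 3457 higher genes. Cypt9 and Cypt10 have identical values and cannot be separated.

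**Figure D1:**
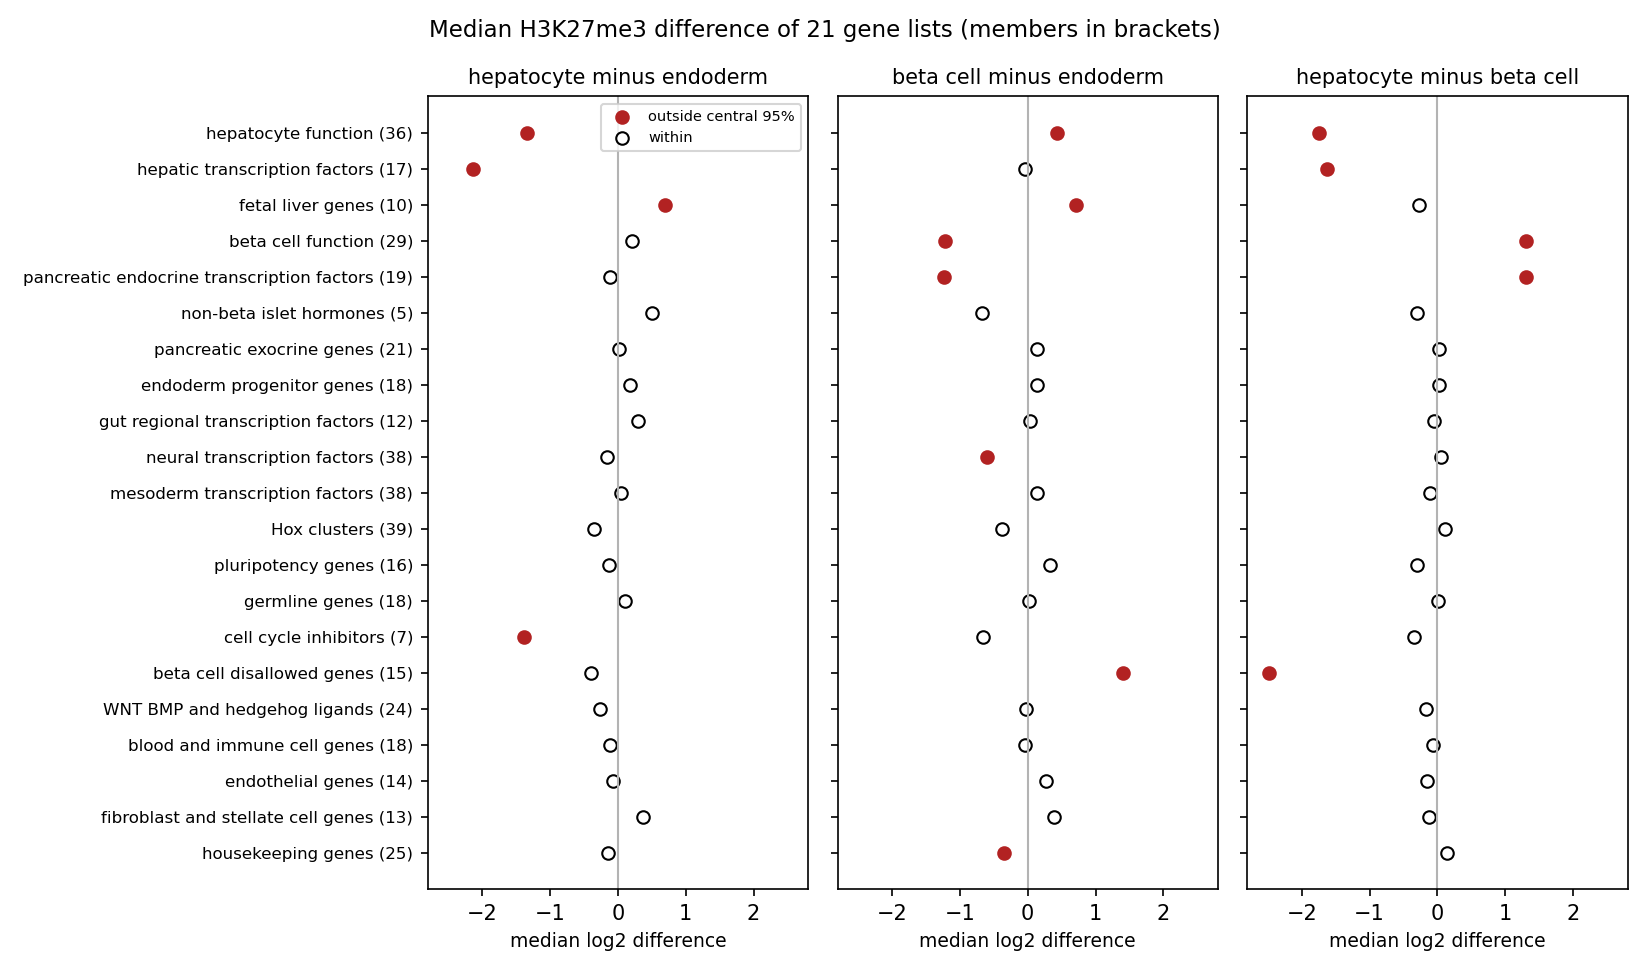
Median log2 difference in H3K27me3 of 21 gene lists in 3 comparisons, 1 panel each, with the number of members in brackets. Filled points mark lists outside the central 95% of 10000 random lists matched on level, and the hepatic factors lie at -2.13 in hepatocytes against endoderm while the endocrine factors lie at -1.24 in beta cells against endoderm.

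The joint pattern across both adult cell types was described with the same counts. Against endoderm, 1469 genes were lower in both adult cell types and 1717 were higher in both, where independent lists would share 493 and 441. The counts depend on scale: after division by the most frequent value, 825 were lower and 3018 higher in both, 78.5% higher in place of 53.9%. With the larger pseudocount 635 were lower and 511 higher, and among genes above the median level 643 and 1139. In the opposite directions, 156 genes were lower in hepatocytes and higher in beta cells, and 222 the reverse. Both comparisons contain the same endoderm values, so such an overlap arises without any effect. With hepatocytes as the shared baseline, 1108 and 1285 genes were lower and higher in both other cell types (408 and 408 for independent lists), and with beta cells 1380 and 1814 (432 and 483). Natd1, Suv39h2, Cebpb, Lrrc26 and Mafa were among the 10 named genes furthest below endoderm in both adult cell types, and Ccl12 was among the 10 furthest above it in both. Cdkn2c was lower in both as well, with ratios of 3.09 in endoderm, 0.27 in hepatocytes and 0.37 in beta cells.

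The third comparison set the adult cell types against each other and asked whether genes of each lineage carry less of the mark in their own cell type. All 4 lineage lists were lower in their own cell type. The hepatic transcription factors had a median difference, hepatocyte minus beta cell, of -1.63 (0 higher and 13 lower of 17), and the hepatocyte function genes of -1.74 (1 and 25 of 36), both below all random lists. Hhex had ratios of 0.10 in hepatocytes and 4.37 in beta cells, Cebpa 0.13 and 3.76, Nr0b2, a bile acid-responsive repressor, 0.16 and 1.83, and Cyp8b1 0.30 and 7.37. The endocrine transcription factors had a median of 1.31 (13 higher and 1 lower of 19) and the beta cell function genes of 1.30 (16 and 0 of 29), both above all random lists. Pdx1 had 7.18 in hepatocytes and 0.22 in beta cells, Pax6 4.74 and 0.26, and the granin Chga 2.67 and 0.26.

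Disallowed genes had the largest median difference of the 21 lists, -2.48, with 11 of 15 lower in hepatocytes and 0 higher. Igfbp4 had ratios of 0.05 in hepatocytes and 1.77 in beta cells, Mgst1, a glutathione transferase, 0.15 and 2.27, and Maf 0.26 and 4.63. The remaining 16 lists were within the random range, including islet hormones (-0.30), exocrine genes (0.03), fetal liver genes (-0.28), Hox genes (0.11), neural factors (0.05), mesodermal factors (-0.11), cell cycle inhibitors (-0.35), and WNT, BMP and hedgehog ligands (-0.17). Cdkn2b was an exception within its list, with 4.48 in hepatocytes and 0.19 in beta cells. Pluripotency genes (-0.30) and germline genes (0.01) were also within the range. The median and mean differed in sign for islet hormones (-0.30 and 0.11), germline genes (0.006 and -0.07) and housekeeping genes (0.14 and -0.01).

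**Figure D2:**
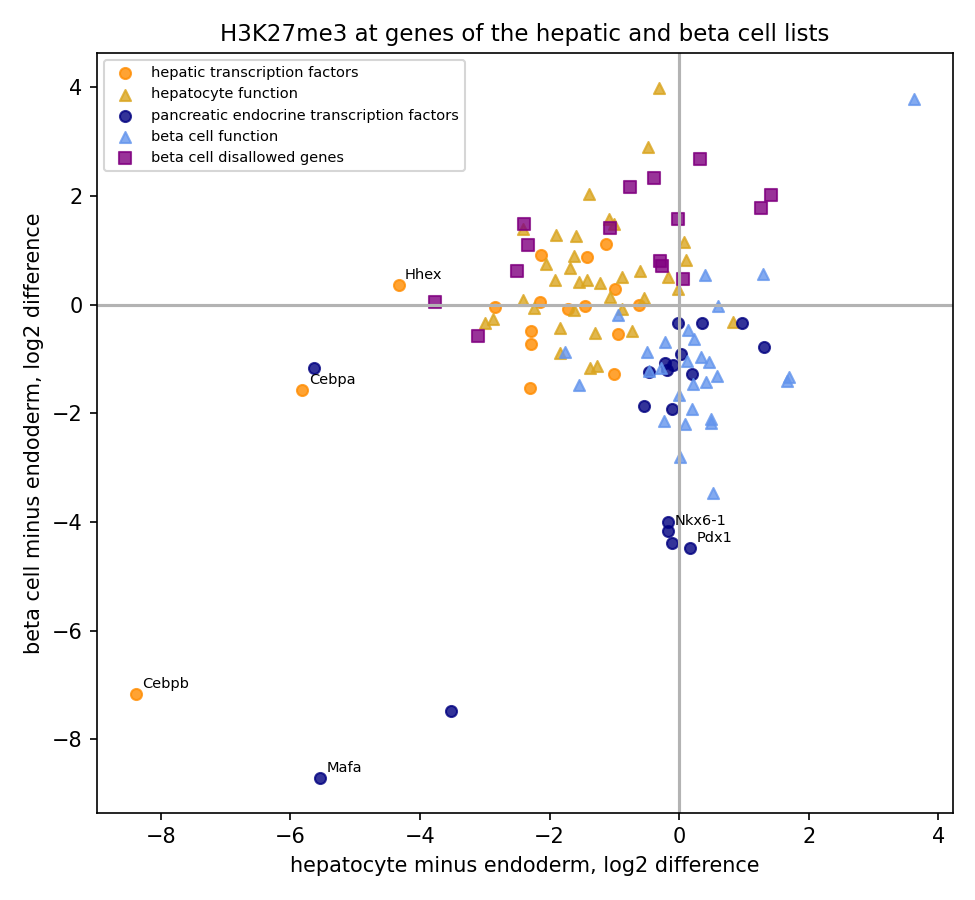
Log2 difference of H3K27me3 from endoderm in hepatocytes (horizontal axis) and in beta cells (vertical axis) for each gene of 5 lists, 1 point per gene. Hepatic factors and hepatocyte genes lie mostly to the left of 0, endocrine factors and beta cell genes lie mostly below 0, and disallowed genes lie mostly above 0, with Ins1 (3.62 and 3.79) as an exception.

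Genes on the X chromosome differed as a group between the adult cell types. In a hand-written list of 90 X-linked genes, chosen after the data had been seen, 78 were higher in hepatocytes than in beta cells and 0 lower, with a median difference of 1.68 (95% bootstrap interval over genes 1.52 to 1.98). Their median ratios were 1.86 in endoderm, 1.91 in hepatocytes and 0.53 in beta cells. The lineage lists hold few such genes, among them Otc, the 1 hepatocyte gene that was higher in hepatocytes (1.63 and 0.69), F9, Pcsk1n and Sytl4. Without hand-listed X-linked genes, the median was -1.91 for hepatocyte function, -1.63 for hepatic factors, 1.30 for beta cell function and 1.39 for endocrine factors.

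Over all genes, 3196 were higher and 3057 lower in hepatocytes than in beta cells. The largest differences toward beta cells included Id1 (0.04 in hepatocytes and 9.82 in beta cells) and Id3 (0.01 and 7.04), inhibitors of helix-loop-helix factors, Ifitm3, an interferon-induced membrane protein (0.02 and 6.09), the chemokine Cxcl1 (0.02 and 3.15), Frat1 (0.13 and 6.75) and Lrg1, a secreted liver glycoprotein (0.12 and 5.71). The other 4 were olfactory receptors. The largest differences toward hepatocytes included C2cd4b (10.4 and 0.09), Lrrc10b (5.61 and 0.12), Eva1b (2.90 and 0.02) and the X-linked Bex1 (8.35 and 0.09) and Nap1l2 (4.41 and 0.06). Scarna10 (630 and 0.93) led this group, and its beta cell ratio is the most frequent value of that column.

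**Figure D3:**
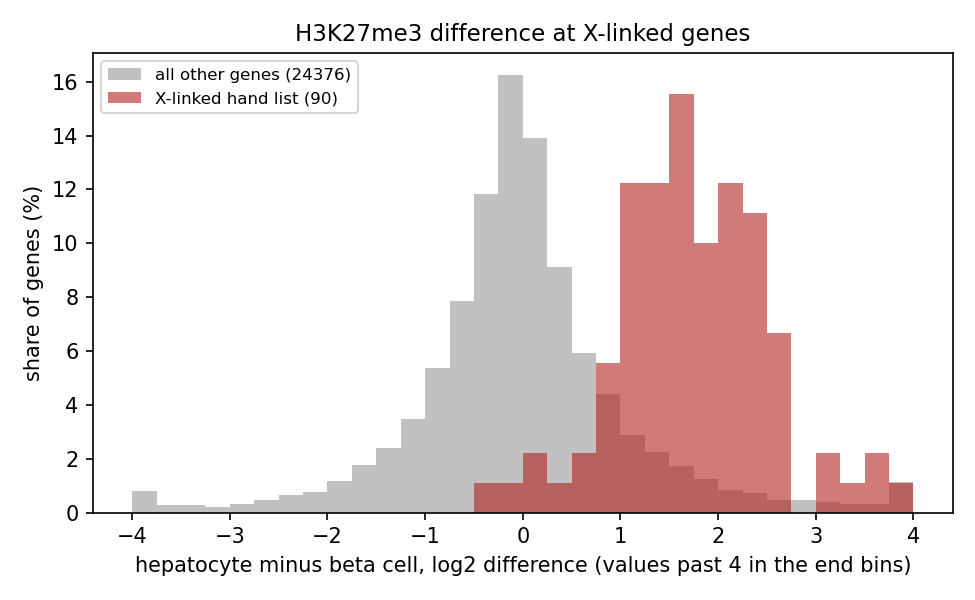
Distribution of the log2 difference in H3K27me3, hepatocyte minus beta cell, for 90 X-linked genes and for all other genes, as the share of genes in each bin (%). The X-linked genes centre on 1.68, and 78 of 90 are at or above 1.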

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

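Genes for hepatocyte function stood apart in opposite directions in the adult cell types: against endoderm, their median log2 difference was -1.34 in hepatocytes (24 of 36 lower) and 0.43 in beta cells (9 of 36 higher). Gene by gene, the difference between these 2 differences is the comparison of hepatocytes with beta cells, with a median of -1.74 below all 10000 random lists. It was not tested against a replicate spread, since each cell type has 1 pooled value. The beta cell side was within the random range among genes above the median level (0.13, 57.3rd percentile), which leaves 12 members.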

How the results depend on the processing

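Dividing columns by their most frequent value, leaving out small RNA or hand-listed X-linked genes, and the pseudocounts for lists were chosen after the data had been seen. The 4 lineage lists in hepatocytes against beta cells stood apart in the same direction in all 9 alternatives (percentiles 0 for both hepatic lists, 100 for beta cell function and 99.97 to 100 for endocrine factors). With the larger pseudocount their medians were smaller: -0.77 for hepatocyte function, -0.84 for hepatic factors, 0.79 for beta cell function and 0.86 for endocrine factors. Of the 16 medians that stood apart, that of housekeeping genes in beta cells against endoderm changed sign (0.0196 after the division), where the shift of all genes by 0.38 accounts for it. Over all 63 medians, 14 changed sign after the division, 11 by the mean, 7 among genes above the median level and 2 in rank percentiles. Over all lists, comparisons and alternatives, 547 of 567 medians kept their call, 14 ended within the random range and 6 newly stood apart.

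Counts depend on threshold and scale. They are given as higher and lower for hepatocyte against endoderm, beta cell against endoderm, and hepatocyte against beta cell, then lower and higher in both adult cell types. The larger pseudocount gave 1252 and 1208, 1547 and 1676, 1520 and 1238, then 635 and 511. Genes above the median level gave 1818 and 1471, 2130 and 2177, 2044 and 1633, then 643 and 1139, with fewer genes compared. The threshold of 1.5 gave 1795 and 1693, 1970 and 2108, 1927 and 1631, then 744 and 918. The threshold of 0.5 gave 5904 and 6402, 6564 and 6696, 5715 and 6285, then 3479 and 3543. Division by the most frequent value gave 5215 and 1897, 5709 and 2346, 3278 and 3011, then 825 and 3018, so hepatocytes against beta cells stayed near 3196 and 3057. Beyond what the smaller gene set, the thresholds and the shift of all genes imply, the cause was not tested. Of the 60 named differences, 6 were under 25 points as rank percentiles.

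No paired analysis was possible because the columns carry 1 pooled value per cell type. For that reason leaving out replicates, limma on 2 cell types and limma without trend were not run. Counting every row, or averaging rows of a symbol, changes nothing, since each symbol occurs once. Depth is unknown, so short genes with few reads cannot be separated from others.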

Other observations

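All tests in this part were chosen after the results had been seen, and the sets come from a scan of 143 symbol families in 3 comparisons or from hand-written lists. A central 95% range leaves 5% of families outside by chance if their genes vary independently, as the random lists of single genes assume. Whether the genes of a family share their signal was not examined, and a shared signal would put more families outside.

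Of the 143 families, 16 were lower in hepatocytes than in beta cells, and 5 of these lay below all 10000 random lists. They were the cytochrome P450 genes (Cyp, 105 genes, median log2 difference -0.72, 46 lower and 2 higher), UDP-glucuronosyltransferases (Ugt, 21 genes, -1.05), carboxylesterases (Ces, 19 genes, -1.16), serpins of the Serpina clade (26 genes, -1.27) and Nat genes (16 genes, -1.29). The other 11 included Hsd (-0.73), aldehyde dehydrogenases (Aldh, -0.63, 9 of 21 lower), carbonic anhydrases (Car, -0.57) and Abhd (-0.42), while aldo-keto reductases (Akr, -0.27, 15.5th percentile), sulfotransferases (Sult, -0.06), Abca (-0.20, 23.7th percentile) and Slco transporters (-0.29) were within the range. As many families, 16, were higher in hepatocytes than in beta cells, and 3 of these lay above all random lists: Rhox, an X-linked homeobox cluster (1.41, 19 higher and 0 lower of 30), Hist (0.58) and Vmn (0.18). Against endoderm, Cyp (-0.56), Ugt (-0.96), Ces (-0.63) and Serpina (-0.41) were lower in hepatocytes, by -18.9, -38.4, -22.2 and -14.8 points in rank percentile. Division by the most frequent value turned the sign of Serpina (0.02), while relative to the median of all genes, which that division moves to 0.38, it was at -0.37. Nat was at -0.28 against endoderm in hepatocytes, by -3.11 rank points and within the random range, and at 0.11 after that division. In beta cells against endoderm, Serpina (0.76, 8 higher and 1 lower) and Nat (0.84) were higher.

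Against endoderm, 8 families lay above all random lists in hepatocytes, and olfactory (Olfr), vomeronasal (Vmn, 0.51) and taste receptor genes (Tas, 1.11) were among them. Keratins (Krt, 54 genes) had a median of 0.58, but 15 of 54 passed the threshold upward and 1 downward, and the median shift in rank percentile was 7.53 points. Keratin-associated proteins (Krtap, 1.21, 28 of 54 higher), late cornified envelope genes (Lce, 1.00, 11 of 21) and Sprr genes (1.08, 9 of 16) were higher in hepatocytes, and also in beta cells (0.78, 0.99 and 0.60). In that order, their median shifts in rank percentile were 10.8, 18.7 and 43.3 points in hepatocytes and 9.04, 10.7 and 17.4 points in beta cells. Histone genes (Hist, 69 genes) were higher in hepatocytes than in endoderm (0.74, 29 higher and 13 lower), and than in beta cells (0.58, 26 higher and 10 lower).

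X-linked genes were higher in hepatocytes than in beta cells by a median of 1.68. Random lists matched on level were below this in 10000 of 10000 draws, which argues against level. These lists come from the same normalized columns, so they cannot test normalization. Normalization and scaling keep the order of genes within a column, and the median difference in rank percentile was 50.6 points, which argues against them. A candidate explanation is a different sex of the source animals, since the inactive X of females carries H3K27me3. The 4 genes known to escape inactivation had a median of 0.69, which is 1.00 below that of the list and goes with that explanation. With 4 genes, the bootstrap interval (0.09 to 0.88) only spans their lowest and highest values, those of Ddx3x and Eif2s3x. All 4 were still higher in hepatocytes than in beta cells. For the 10 Y-linked genes, the explanation predicts the most frequent value in 1 of the 2 columns only. Only 3 were at that value in hepatocytes and 0 in beta cells. Their ratios were 0.92 to 1.24 in hepatocytes, near the most frequent value, against 0.29 to 1.10 in beta cells. Their median difference was 0.73 (99.2nd percentile, interval -0.02 to 1.13). It does not bear on sex, since a ratio without reads has an arbitrary size. With these few genes the sex of the animals cannot be told apart from other causes.

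Olfactory receptor genes (1125) were higher than in endoderm by a median of 1.00 in hepatocytes and 0.83 in beta cells. Level does not account for it (10000 of 10000 matched lists lay below in both), and neither does normalization or scaling of the ratios, which keeps the order of genes within a column: the median shifts in rank percentile were 31.5 and 16.3 points (intervals 25.8 to 35.5 and 12.6 to 21.7). Few reads over short genes may contribute: the short vomeronasal Vmn1r genes had medians of 1.15 and 0.49 (intervals 1.03 to 1.33 and 0.19 to 0.76), while the longer Vmn2r genes had -0.10 and -0.03. The outcomes of the level and rank tests were already known when they were chosen. No biological explanation was tested.

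In endoderm, 63 genes other than small RNAs had ratios above 20, against 1 in hepatocytes and 12 in beta cells. Their median rank percentile was 99.1 in hepatocytes and 98.3 in beta cells, which argues against counting noise alone for the high rank of the set. It cannot decide on noise in the size of the endoderm ratios, since a gene high in every column could still be inflated in 1. That median does not speak for Natd1, Cebpb and Suv39h2, the 3 genes furthest below endoderm in hepatocytes, whose rank percentiles were 35.0, 12.9 and 44.9 in hepatocytes and 42.0, 59.4 and 63.8 in beta cells, and for which noise stays open. Inflation by a low input in endoderm was not tested, since input coverage was not analysed here. Quantile normalization gives each column the same top values (99th percentile 7.41, maximum 1428). In hepatocytes and beta cells, small RNA genes therefore held most of the ratios above 20. For the 63 genes, a median log2 difference of -3.74 in hepatocytes against endoderm went with a median shift of -0.65 points in rank percentile. Their fold differences from endoderm thus depend on the steep upper tail shared by the columns.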
